A study of Homo sapiens with 6 samples.

How the data were processed

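RNA from 6 samples of human hepatic stellate cells, 3 control and 3 treated with TGFβ for 48 h, was sequenced as Illumina libraries per the labels' protocols. The authors deposited one table of raw read counts per gene, whole numbers that are not normalized. Per the submitters' processing notes, TopHat2 2.1.0, featureCounts and edgeR were used with builds GRCh38 and hg38; the notes give neither their roles nor their order. The annotation release, the strand setting and the handling of reads that fall in more than one gene are not given in the sources used here. Gene names, starts and ends are those of the deposited table. The coding length and the start and stop of each gene are deposited as other values without a sample.

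Groups were taken from the treatment labels. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 19713 of 64253 rows, scaled with TMM factors and fitted with glmQLFit (robust) on the group alone. P-values from glmQLFTest were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM use TMM-scaled library sizes. The 36 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members (33) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry.

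Named genes were IGFBP3, ACTA2, COL1A1, SMAD7, TGFB1, TIMP1 and PDGFRB; the 8 largest rises and 8 largest falls among changed genes with at least 5 CPM on average and no overlap between groups; 2 or 3 members of the leading lists by size of change; and 1 member of each other list. PTPRC, TYROBP, CD14 and CD3E belong to a test of immune transcripts whose genes were set before their values were seen. Every other gene named was chosen after its values were seen, among them FN1, IGFBP4, IGFBP5, IGFBP7, PAPPA, TAGLN, CNN1, TPM1, PMEPA1, INHBA, TGFBR2, COL4A1, COL4A2, COL4A5, COL4A6, ELN, DCN, NID2, SERPINE2, MMP2, ADAMTS1, PLAU, RDH10, CCL2, PTGS2, IL6, C3, NQO1, TXNRD1, MKI67, TOP2A, PSAT1 and PDGFRA.

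Simulated counts with the means, library sizes and dispersions of these 19713 genes and 200 changed genes were used to test the script for the comparison of TGFβ with control. It recovered 52.2% of 1.5-fold, 79.1% of 2-fold and 93.9% of 4-fold changes. Of its calls 8.54% were false, against an adjusted p threshold of 0.05. The simulation held far fewer changed genes than the 45.2% called in the data. Of 100 random lists 3 had a camera p under 0.05. The simulated genes were drawn independently, so this could not check the preset correlation. The common biological coefficient of variation was 9.29%. At the depths of these libraries 3 counts, the limit that a count of 0 allows, correspond to between 0.0536 and 0.0782 CPM of the raw total; floors and counting intervals cover counting error only.

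Gene types and overlaps were taken from GENCODE release 29 on GRCh38, which holds 56591 of the gene identifiers, 52993 of them with the same start and end. Across genes with over 50% of their exonic bases overlapped on the opposite strand, the log2 fold changes of the gene and its partner correlated with a Spearman coefficient of 0.867 (907 genes), against 0.198 for neighbours without overlap (13324 pairs); genes are not independent replicates. With up to 20% of exonic bases overlapped on the opposite strand the coefficient was still 0.641 (4461 genes). Antisense and overlapping genes are therefore uncertain, also below 50% overlap.

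Alternatives were DESeq2 size factors, upper-quartile factors, total counts, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust estimation, a replicate block and leaving out each library. Added after seeing the data were total counts without the 10 most abundant genes, leaving out overlapped genes, leaving out libraries for the composition, and the family scan. XIST and Y-linked genes stayed in the model and are not reported. Some genes, one of them fixed in advance, are not reported here.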

Results

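RNA sequencing was performed on human hepatic stellate cells, the vitamin A storing pericytes of the liver that become matrix-producing myofibroblasts in fibrosis. The cells were obtained from a company and were starved of serum overnight. One group of 3 samples served as control and another group of 3 samples received recombinant human TGFβ, a profibrotic cytokine, for 48 h. The counts summed to between 38380963 and 53750238 per control library and between 40219026 and 56012568 per TGFβ library. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 9.8 to 24.5), so none appeared to be a second copy of another; libraries made separately from 1 culture can also differ by more than this noise. Of 64253 genes in the table, 19713 had enough counts to be tested.

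TGFβ was accompanied by a broad change of the transcriptome. Of the contractile and actin genes 22 of 25 rose and 1 fell, of the fibril-forming collagens 7 of 11 rose and 0 fell, and of the SMAD target and feedback genes 13 of 19 rose and 4 fell. In the cytokine and chemokine list, which also held related genes, 18 of 25 members fell and 5 rose. Interferon response genes fell in 17 of 23 cases and rose in 1. Complement and acute phase genes fell in 10 of 12 and rose in 2. Genes of the quiescent state fell in 14 of 20 and rose in 5. These 7 lists passed camera's test at its preset correlation, and none did with an estimated correlation (adjusted p = 0.367 for each). FN1, which encodes fibronectin, rose from 8400 ± 1600 to 61600 ± 4800 CPM, a count scaled to a common library size (mean ± SD, n = 3 per group). IGFBP3 rose 4.62-fold and ACTA2, the smooth muscle actin of myofibroblasts, 6.96-fold. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 8915 genes (45.2% of those tested) changed, 4499 of them higher and 4416 lower with TGFβ. At least 2-fold changes were found for 2786 genes, of which 1153 were higher and 1633 lower. When libraries were scaled by their total counts alone, the split was 2267 higher and 8745 lower, because that scaling moved the median log2 fold change of all genes by -0.27; changes are given relative to the TMM scale. The 3 control and the 3 TGFβ values did not overlap for 53.9% of tested genes, against 10% by chance.

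The series singles out IGFBP3, a carrier protein of insulin-like growth factors, as a leading TGFβ target. The study chose the gene on these samples, so its change here is not independent evidence. IGFBP3 (ENSG00000146674; GRCh38 chromosome 7, 45912245 to 45921874) had 1766 ± 146 CPM in control and 8162 ± 508 CPM in TGFβ libraries (SD, n = 3 each). Its log2 fold change was 2.21 with a standard error of 0.0916 (edgeR adjusted p = 1.38e-11), and it was higher in 3 of 3 TGFβ libraries than in any control. Among the 4499 higher genes it ranked 346 by fold change, 82 by p-value and 5 by gain in CPM. Within the IGF axis list, 7 of 17 tested members rose and 9 fell, over all genes and also adjusted over the list alone. The list had no direction of its own by camera (adjusted p = 0.495), and its median log2 fold change of -0.31 and mean of 0.06 differed in sign. Scaling by total counts gave 4 higher and 10 lower members and a median of -0.58. IGFBP5 fell from 13700 ± 970 to 4870 ± 350 CPM and IGFBP4 from 3200 ± 79 to 1090 ± 56 CPM, whereas IGFBP7 rose from 354 ± 57 to 878 ± 59 CPM. PAPPA, a protease that cleaves IGF-binding proteins, had a log2 fold change of -1.53. IGFBP2 fell by 2.02 on the log2 scale. IGF1 rose from 0.183 ± 0.0943 to 15.5 ± 2.32 CPM, but 82.4% of its exonic bases overlap HELLPAR on the opposite strand, so that reads of the pair cannot be assigned with certainty.

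**Figure D1:**
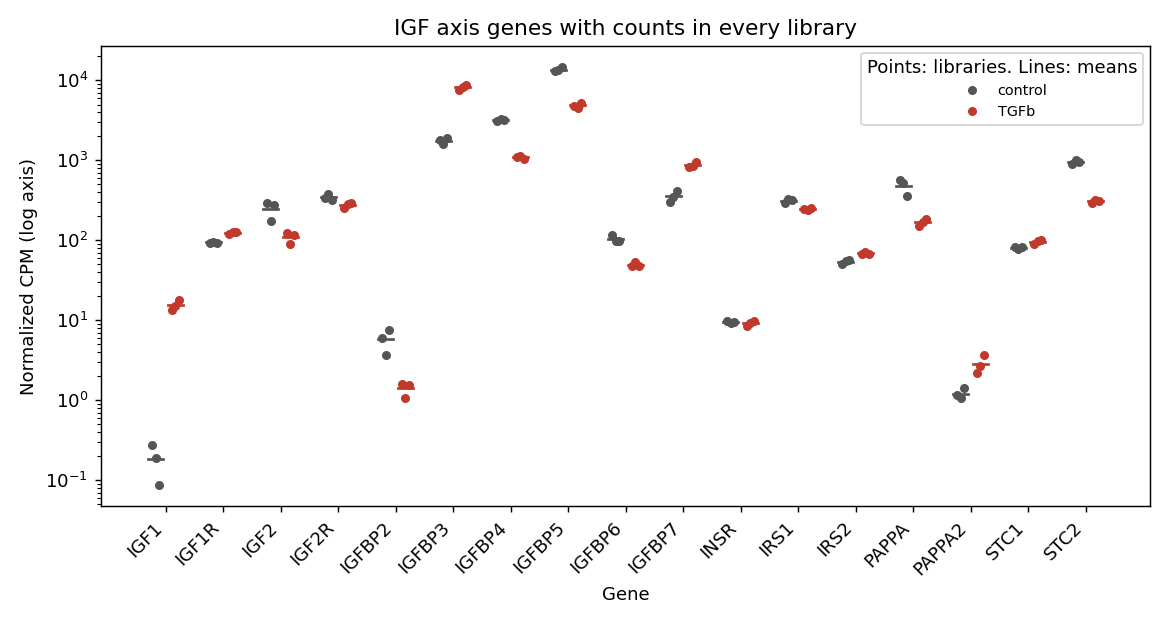
Normalized CPM on a log axis for each IGF axis gene with counts in every library, with 3 control (grey) and 3 TGFβ (red) libraries as points and group means as lines. IGFBP3 averaged 1766 CPM in control and 8162 CPM in TGFβ libraries, while IGFBP5 averaged 13700 and 4870 CPM; on scaling by total counts 4 members were higher and 10 lower.

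Of the other genes fixed in advance, ACTA2 (chromosome 10, 88935074 to 88991390) rose from 420.2 ± 48.8 to 2923 ± 46.7 CPM, with a log2 fold change of 2.80 (SE 0.0944). COL1A1, a chain of type I collagen, rose by 1.02 on the log2 scale (SE 0.109) and TGFB1 itself by 1.34 (SE 0.0721). TIMP1, an inhibitor of matrix metalloproteinases, rose by 0.41 (edgeR adjusted p = 4.98e-04), a call that was lost on scaling by total counts (0.14, adjusted p = 0.0798). PDGFRB, a stellate cell growth factor receptor, had 365.8 ± 38.5 and 356.6 ± 5.32 CPM and did not pass the test (log2 fold change -0.04, adjusted p = 0.746). On scaling by total counts it was called lower (-0.31, adjusted p = 0.00134).

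**Figure D2:**
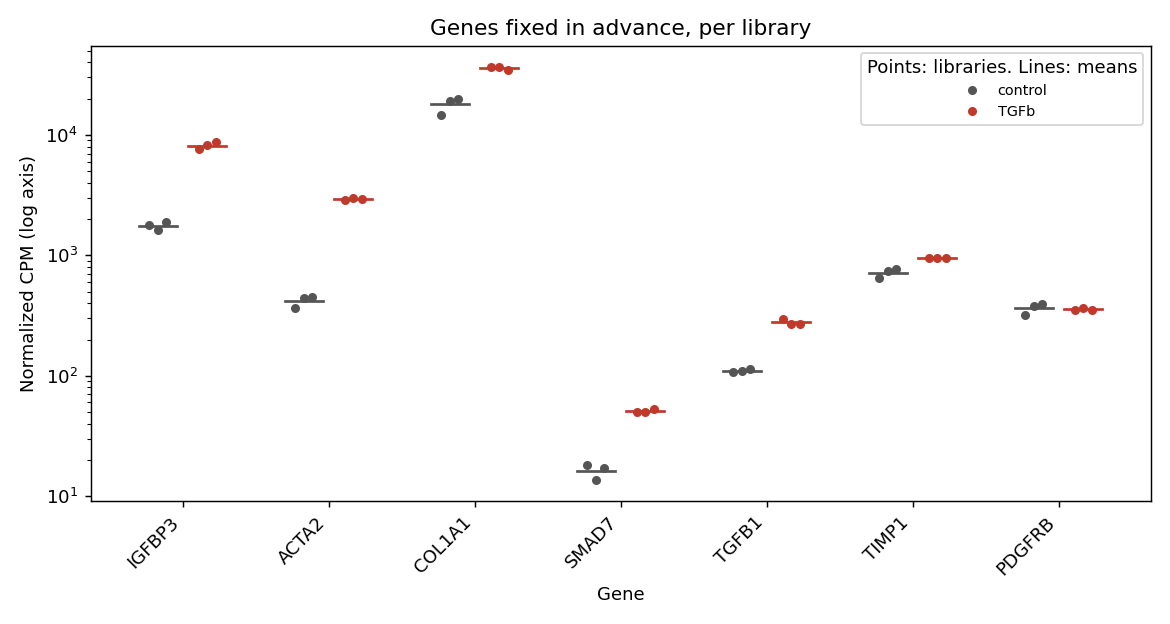
Normalized CPM on a log axis for 7 genes fixed in advance, with 3 control (grey) and 3 TGFβ (red) libraries as points and group means as lines. All but PDGFRB lay higher in each TGFβ library than in each control library; PDGFRB averaged 365.8 and 356.6 CPM.

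In the contractile and actin list, 22 of 25 members rose and 1 fell, with the same counts adjusted over the list alone. Its median log2 fold change was 1.13 (camera adjusted p = 2.97e-09; adjusted p = 0.367 with an estimated correlation). MYH11, smooth muscle myosin, had a log2 fold change of 4.53, and TAGLN, CNN1 and TPM1 had 1.75, 2.09 and 2.06. MYLK, the kinase of myosin light chains, fell by 0.30. Of 19 SMAD target and feedback genes, 13 rose and 4 fell, also adjusted over the list alone (median 1.65, camera adjusted p = 6.57e-04; adjusted p = 0.367 with an estimated correlation). With total counts as the scale 11 rose and 6 fell. The inhibitors SMAD7 and PMEPA1 rose by 1.65 and 3.42, and BHLHE40 by 3.46. LDLRAD4 rose from 4 counts over the control libraries to 637. SMAD3, a transducer of the pathway, fell by 3.07 on the log2 scale (SE 0.0752). Among TGFβ ligands and receptors 9 of 18 rose and 5 fell (camera adjusted p = 0.171), INHBA by 2.60 upward while TGFBR2 fell by 1.03. The median of 0.26 became -0.02 on scaling by total counts. The list then passed the threshold as higher relative to other genes (camera adjusted p = 0.0279). On the TMM scale its adjusted p was 0.513 with an estimated correlation.

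Transcripts of matrix genes changed in both directions. Of 11 fibril-forming collagens 7 rose and none fell, and 9 rose adjusted over the list alone (median 0.75, camera adjusted p = 6.05e-04; adjusted p = 0.367 with an estimated correlation). With total counts as the scale 7 were higher and 1 lower, and the median was 0.49. COL5A1 and COL11A1 had log2 fold changes of 1.98 and 1.90. In collagen processing and crosslinking, 17 of 27 genes rose and 4 fell, with 20 and 4 adjusted over the list alone (median 0.58, camera adjusted p = 7.27e-05; adjusted p = 0.490 with an estimated correlation). The median was 0.30 on scaling by total counts, with 15 higher and 5 lower. P4HA3, a prolyl hydroxylase, and PCOLCE2 rose by 2.48 and 2.44, and LOXL4 fell by 0.71. Among other collagens 10 of 18 rose and 5 fell (camera adjusted p = 0.0894). On scaling by total counts 8 rose and 7 fell, and the list passed the threshold (camera adjusted p = 0.00541; on the TMM scale adjusted p = 0.434 with an estimated correlation). The basement membrane chains COL4A1 and COL4A2 rose by 2.03 and 1.52, whereas COL4A5 and COL4A6 fell, with log2 fold changes of -1.88 and -2.84. Matrix glycoproteins and proteoglycans had 21 of 40 members higher and 13 lower (camera adjusted p = 0.0768). COMP and ELN rose by 4.97 and 4.27 and DCN and NID2 fell, with log2 fold changes of -2.52 and -3.30. This list passed the threshold on scaling by total counts (20 higher and 17 lower, adjusted p = 0.000463) and without control replicate 2, control replicate 3 or TGFβ replicate 2 (adjusted p = 0.0332, 0.0329 and 0.0459), but not with an estimated correlation (adjusted p = 0.513). Integrins and focal adhesion genes had 12 of 23 higher and 3 lower, with 14 and 3 adjusted over the list alone (camera adjusted p = 6.36e-04; adjusted p = 0.490 with an estimated correlation), with ITGA11, a collagen receptor, at 3.67. Scaling by total counts gave 10 higher and 6 lower, and the list median of 0.32 became 0.05. ITGA8 had 107 counts in control and 3 in TGFβ libraries, a ratio of 29.2-fold lower (95% Clopper-Pearson interval 9.72 to 144, counting error only). Matrix proteases and inhibitors split into 14 higher and 10 lower of 28 (camera adjusted p = 0.244). With total counts as the scale these were 12 and 11, and the list passed the threshold (camera adjusted p = 0.00841; on the TMM scale adjusted p = 0.580 with an estimated correlation). SERPINE2 and MMP2 rose by 4.95 and 1.70, and ADAMTS1 and PLAU fell, with log2 fold changes of -4.33 and -2.40. In the hyaluronan list 5 of 10 genes rose and 3 fell (camera adjusted p = 0.418), and CEMIP, a hyaluronan-degrading protein, fell from 370.3 ± 102 to 8.50 ± 0.334 CPM.

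Genes of the quiescent stellate cell and of retinoid handling fell in 14 of 20 cases and rose in 5, also adjusted over the list alone (median -1.55, camera adjusted p = 6.77e-04; adjusted p = 0.367 with an estimated correlation). Of the list's 34 members 20 had enough counts to be tested. The control cells also had 420.2 CPM of ACTA2 and 17890 CPM of COL1A1, and how quiescent they were was not tested. PPARG, a lipid regulator, fell from 15.4 ± 1.32 to 0.524 ± 0.0754 CPM. HGF, hepatocyte growth factor, fell by 4.17 and RDH10, a retinol dehydrogenase, fell by 3.03, while GATA6 rose by 2.15. Of 25 tested members of the cytokine and chemokine list 18 fell and 5 rose, also adjusted over the list alone. The median was -2.43, unchanged with genes at 0 set to their bound (camera adjusted p = 2.37e-04, and adjusted p = 0.367 with an estimated correlation). These members include VCAM1, ICAM1, TNFAIP3, NFKBIA and SOD2, which fell, and PTGS2 and TNFAIP6, which rose. None of these is a cytokine or chemokine. CXCL10 had 444 counts in control and 0 in TGFβ libraries and was at least 121-fold lower against a floor of 3 counts over the group. VCAM1 and CCL2 fell, with log2 fold changes of -5.47 and -4.66. The lymphocyte markers IL7R and CD4 also fell, with log2 fold changes of -0.95 and -1.02. The risers included IL11, a cytokine of fibroblast activation, from 66.5 ± 5.22 to 1598 ± 98.4 CPM, and PTGS2 and IL6 by 3.83 and 1.08. Interferon response genes fell in 17 of 23 cases and rose in 1, also adjusted over the list alone (median -1.15, camera adjusted p = 2.47e-05; adjusted p = 0.367 with an estimated correlation). MX1 and IFIT1 fell, with log2 fold changes of -3.79 and -3.57, and IFIH1, a sensor of double-stranded RNA, rose by 1.10. Complement and acute phase genes had 10 of 12 members lower and 2 higher, also adjusted over the list alone (median -1.22, camera adjusted p = 6.77e-04; adjusted p = 0.367 with an estimated correlation), with PTX3 at -4.62 and C3 at -2.24. In the oxidant and antioxidant list 17 of 24 fell and 4 rose, with 17 and 5 adjusted over the list alone (median -0.72, camera adjusted p = 6.36e-04; adjusted p = 0.434 with an estimated correlation). With total counts as the scale 18 fell and 1 rose. NQO1, TXNRD1 and SOD2 fell, with log2 fold changes of -1.63, -1.77 and -2.43, and NOX4, which makes hydrogen peroxide, rose from 4.45 ± 0.456 to 145.4 ± 11.7 CPM.

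Proliferation genes rose in 28 of 34 cases and fell in 1, also adjusted over the list alone (median 0.61, camera adjusted p = 8.86e-08; adjusted p = 0.367 with an estimated correlation). On scaling by total counts 20 rose and 2 fell, with a median of 0.33. CCNA2, MKI67 and TOP2A had log2 fold changes of 1.69, 0.71 and 0.61, and AURKA fell by 0.48. In the unfolded protein response and secretory list 19 of 27 rose and 1 fell, also adjusted over the list alone (median 0.49, camera adjusted p = 1.36e-05; adjusted p = 0.367 with an estimated correlation). The split was 15 higher and 5 lower and the median 0.22 on scaling by total counts. CREB3L2 and DNAJB9 rose by 1.35 and 1.34, and ATF3 fell by 0.92. Cholesterol synthesis genes rose in 16 of 22 cases and fell in 3 (camera adjusted p = 9.92e-04; adjusted p = 0.490 with an estimated correlation), INSIG1 by 1.91, against 11 and 4 on scaling by total counts. Glycolysis genes rose in 14 of 24 cases and fell in 3 (camera adjusted p = 0.00125; adjusted p = 0.513 with an estimated correlation), PFKFB4 by 2.22. On scaling by total counts 10 rose and 7 fell, and the list median of 0.38 became 0.11. Genes of serine, glycine and proline synthesis and ATF4 targets rose in 18 of 31 cases and fell in 6 (camera adjusted p = 0.0027; adjusted p = 0.513 with an estimated correlation), among them SLC1A4 by 1.64 and PSAT1 by 0.93, against 14 and 9 on scaling by total counts. Counts for these last 3 lists were the same adjusted over the list alone.

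**Figure D3:**
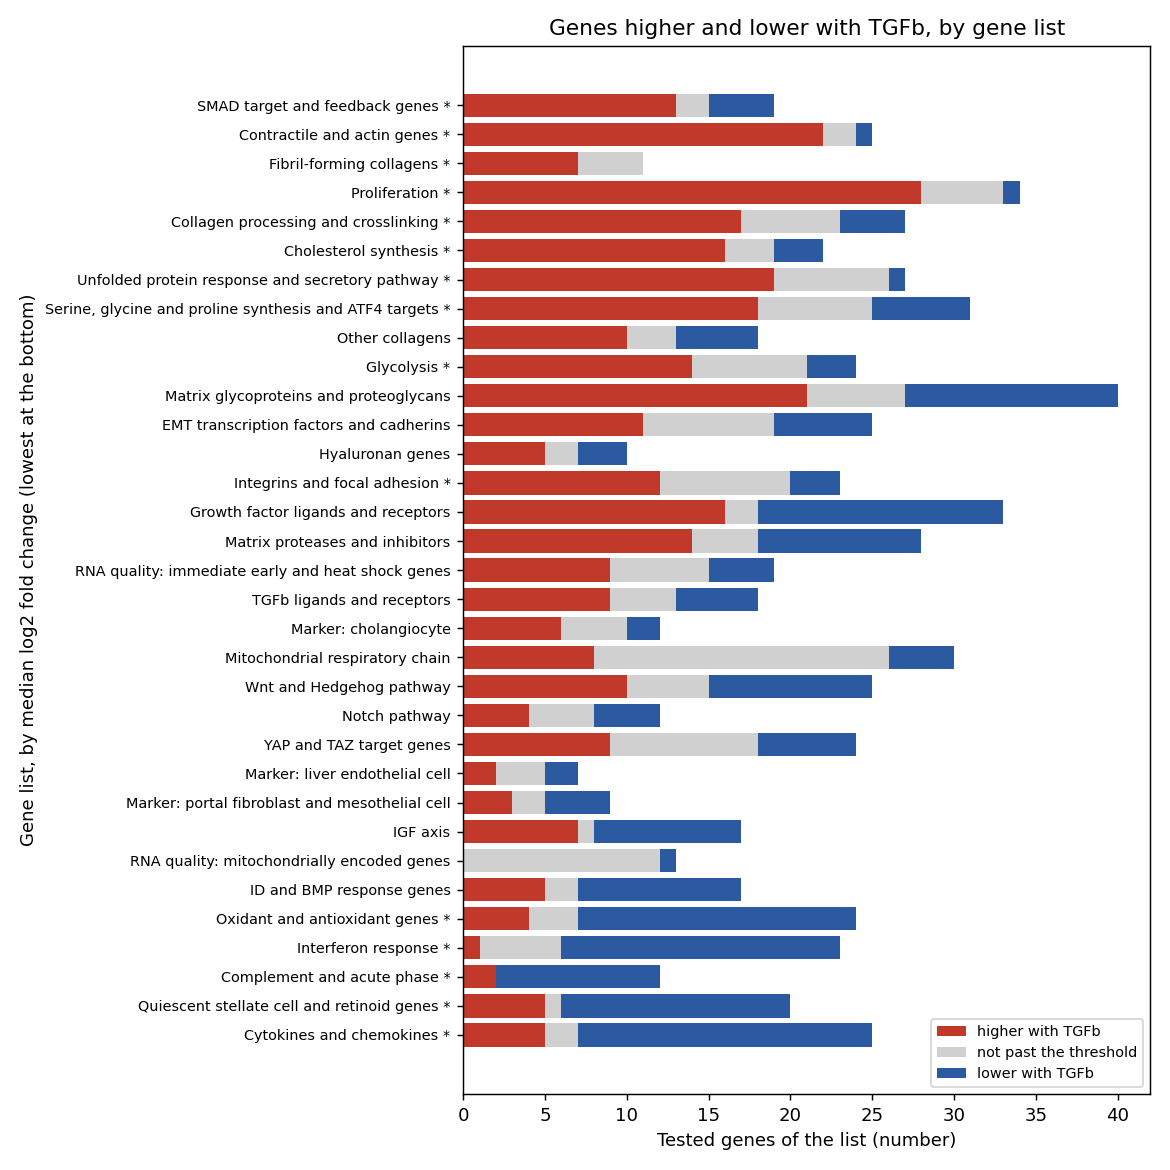
Number of tested genes per gene list that were higher (red), lower (blue) or not past the threshold (grey) with TGFβ, for the 33 lists with at least 5 tested members, ordered by median log2 fold change; an asterisk marks camera adjusted p under 0.05. Contractile genes had 22 of 25 members higher and the cytokine and chemokine list had 18 of 25 lower. On scaling by total counts these were 20 and 18.

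Other lists held genes moving both ways. Counts adjusted over the list alone were 12 and 8 for EMT factors, 6 and 10 for ID and BMP genes, 15 and 10 for matrix proteases and inhibitors and 0 for mitochondrially encoded genes, and the same as over all genes for the rest of the lists without a camera call. Of 33 growth factor ligands and receptors 16 rose and 15 fell (camera adjusted p = 0.835; median 0.30, mean -0.03), PDGFRA falling by 1.08. With total counts as the scale 14 rose and 16 fell, with a median of 0.03. ID and BMP response genes had 5 of 17 higher and 10 lower (camera adjusted p = 0.244), and BMP4 fell by 5.17. Wnt and Hedgehog genes split 10 and 10 of 25 (camera adjusted p = 0.495), and 10 and 12 on scaling by total counts. WNT11 had 0 counts in control and 62 in TGFβ libraries and was at least 25.3-fold higher against the floor of 3 counts. EMT transcription factors and cadherins had 11 of 25 higher and 6 lower (camera adjusted p = 0.116). Scaling by total counts turned this to 9 higher and 11 lower. The list then passed the threshold as higher relative to other genes (camera adjusted p = 0.0163). On the TMM scale its adjusted p was 0.554 with an estimated correlation. FOXS1, a member with 0 control counts, was at least 17.5-fold higher. YAP and TAZ targets had 9 of 24 higher and 6 lower (camera adjusted p = 0.418; median -0.04, mean 0.21), with ANKRD1 at 2.42. On scaling by total counts the balance turned to 7 higher and 13 lower, with a median of -0.31. Notch genes split 4 and 4 of 12 (camera adjusted p = 0.757), while scaling by total counts gave 2 higher and 6 lower. DLL1 fell by 2.51, from 43 counts over the control libraries to 6. Nuclear genes of the respiratory chain had 8 of 30 higher and 4 lower (camera adjusted p = 0.405), with CYCS at 0.62; on scaling by total counts 1 was higher and 17 lower.

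Among all genes with at least 5 CPM on average and no overlap between groups, the largest rises included PLN, ACTC1, ZPLD1, KAL1 (now ANOS1), KANK4, COL10A1 and EGR2, besides IGF1. PLN, which regulates the calcium pump of muscle, had 3 counts in control and 1443 in TGFβ libraries, a ratio of 588 (95% Clopper-Pearson interval 201 to 2850, counting error only). ACTC1, cardiac actin, rose from 0.837 ± 0.252 to 232.1 ± 31.1 CPM; as a near copy of ACTA2 it could share reads, but its ratio to control far exceeded that of ACTA2. The largest falls were CLDN11 (-6.11), SHISA3 (-5.78), KCNJ2 (-5.76), VCAM1 (-5.47), CEMIP (-5.45), BMP4 (-5.17), SERPINB10 (-5.14) and SERPINB2 (-4.90). SERPINB10 and SERPINB2 share 20.3% of the exonic bases of the former, so their counts are not independent.

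Among markers of other liver cells, none of 4 tested hepatocyte markers passed the test, the most abundant being CPS1 at 13.4 ± 1.30 and 14.3 ± 2.92 CPM. All 3 tested lymphocyte markers fell, IL7R from 57.9 ± 4.8 to 30.1 ± 2.5 CPM, CD4 from 32.2 ± 2.8 to 15.9 ± 0.8 CPM and KLRD1 from 1.08 ± 0.38 to 0.422 ± 0.19 CPM. Of 2 tested macrophage markers CSF1R rose by 2.40 on the log2 scale, but only from 23 counts over the control libraries to 103. CD68 fell from 31.3 ± 2.4 to 18.2 ± 1.5 CPM. Endothelial markers split 2 and 2 of 7 (camera adjusted p = 0.584), TEK falling from 102.3 ± 19.9 to 12.5 ± 2.29 CPM. Cholangiocyte markers had 6 of 12 higher and 2 lower (camera adjusted p = 0.244; median 0.22, mean -0.08). These were 5 and 4 on scaling by total counts, with a median of -0.05. The list then passed the threshold as higher relative to other genes (camera adjusted p = 0.0279). On the TMM scale its adjusted p was 0.513 with an estimated correlation. CFTR fell from 156 to 2 counts, 63.7-fold (95% Clopper-Pearson interval 17.4 to 532). Portal fibroblast and mesothelial markers had 3 of 9 higher and 4 lower (camera adjusted p = 0.960; median -0.25, mean 1.04), PI16 rising from 7 to 643 counts, and the median was -0.53 on scaling by total counts. Immediate early and heat shock genes, fixed as a possible sign of RNA handling, had 9 of 19 higher and 4 lower (camera adjusted p = 0.0592). Handling and a response to TGFβ cannot be told apart in this list, whose member EGR2 was among the largest rises (6.1). A split of 6 higher and 8 lower was found on scaling by total counts, with the median moved from 0.281 to 0.0078. The list was then past the threshold as higher relative to other genes (camera adjusted p = 0.027). It also passed without control replicate 3, TGFβ replicate 2 or TGFβ replicate 3 (adjusted p = 0.031, 0.0281 and 0.0409), but not with an estimated correlation (adjusted p = 0.513). Mitochondrially encoded genes took 2.01 ± 0.213% of control and 1.27 ± 0.344% of TGFβ counts (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Their list had a camera adjusted p of 0.0831, which was 0.0356 without TGFβ replicate 1 and 0.0284 without TGFβ replicate 3, while with all libraries and an estimated correlation the adjusted p was 0.708. Of the 13 such genes MT-CO1 alone passed the test (-0.63, adjusted p = 0.0208; 3 passed on scaling by total counts), and it no longer did without control replicate 1 (-0.68, adjusted p = 0.162) or without control replicate 3 (-0.54, adjusted p = 0.0741). The 10 most abundant genes took 8.29 ± 0.553% of control and 15.7 ± 0.169% of TGFβ counts (exact permutation p = 0.1), FN1 alone 0.921 ± 0.155% and 5.60 ± 0.311% (exact permutation p = 0.1).

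No list call held with an estimated correlation (smallest adjusted p = 0.367), whereas fry, which tests a list without comparing it with other genes, gave 28 lists with a direction. Genes with overlapping exons were not independent in the counts: the antisense ACTA2-AS1 had the same log2 fold change as ACTA2 (2.80). Leaving out genes with over 50% of exonic bases overlapped, a choice made after seeing the data, left 8298 changed genes of 17815. That cut keeps many correlated pairs. ACTA2 itself overlaps by 17.3%, and with up to 20% overlapped on the opposite strand the Spearman coefficient was 0.641 (4461 genes).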

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

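The tests without the 10 most abundant genes in the totals, without overlapped genes and of the composition with a library left out were chosen after seeing the data. Under 9 settings chosen in advance and 6 fits that each left out a library, the number of changed genes stayed within 1.5 times 8915, and genes shared with those 8915 had the same sign in each setting. Scaling by total counts gave 2267 higher and 8745 lower genes, which follows from the shift of all genes by -0.27 that this scaling makes. The same scaling gave 22 lists, among them the 15. Added were EMT factors, cholangiocyte markers, matrix glycoproteins, matrix proteases, other collagens, immediate early genes and TGFβ ligands. Each added list passed as higher relative to other genes, although this scaling moved the lists and the other genes down alike. The median of EMT factors went from 0.35 to 0.08, and that of all genes from -0.007 to -0.28. Why these lists then passed was not tested. Their camera adjusted p ranged from 0.000463 to 0.0279, against 0.0592 to 0.244 on the TMM scale at the preset correlation. With an estimated correlation it was 0.434 to 0.580 on the TMM scale. An estimated correlation left 0 of the 15 lists past the threshold and fry gave 28. Correlation between genes was not the whole cause of every lost call. The quiescent list had an estimated correlation of 0.0116, close to the preset 0.01, yet its unadjusted camera p rose from 0.000246 to 0.0224. The test with an estimated correlation thus differs from the preset one in more than the correlation. What else differs was not tested, so a call lost there does not show that correlation removed it. Leaving out a library gave between 7679 and 8683 changed genes, 3887 to 4460 higher, 3792 to 4459 lower, 15 to 17 lists, and an IGFBP3 log2 fold change of 2.14 to 2.26. Over all settings IGFBP3 ranged from 1.93 to 2.26. Among 156 single genes recomputed none changed direction past the threshold. Calls lost were TIMP1, PHGDH and ME1 with total counts, MT-CO1 without control replicate 1 or 3, IGF2 without control replicate 3 (adjusted p = 0.0503), and IRF9, whose main adjusted p of 0.048 was lost with DESeq2, limma-voom, no robust estimation and 4 left-out libraries. PDGFRB and DDX58 were gained with total counts and ISG15 without control replicate 3. With a replicate block 8798 genes changed (4395 higher, 4403 lower). Deviations of same-numbered samples correlated at 0.031, 0.11 and -0.024, against -0.14 to 0.096 for differently numbered samples. These values showed no clear pairing but cannot exclude it. The labels do not say whether equal numbers pair the samples. The block gave 16 lists, the mitochondrially encoded list being added (camera adjusted p = 0.0186, against 0.0831 without the block). Without the block its adjusted p was 0.708 with an estimated correlation. The table has no row that names no gene, so counting such rows in the totals could not change the composition. Depth limits genes near 3 counts per group, such as PLN.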

Other observations

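The family scan, the overlap comparison and the tests of NRF2 and NF-kB target genes were chosen only after the results above were seen; the members of both target lists were fixed before any of their values were looked at. Some of the most abundant transcripts fell with TGFβ outside the themes above. The ferritin chains FTL and FTH1 fell, with log2 fold changes of -1.55 and -1.75, EPAS1, a hypoxia-inducible factor, had -2.51, QSOX1, a secreted sulfhydryl oxidase, had -1.42, and SFRP1, a Wnt antagonist, had -3.12. A scan of 127 families of protein-coding genes that share a symbol stem found 5 past an adjusted p of 0.05 by camera and 0 with an estimated correlation (smallest adjusted p = 0.91). TNF receptor genes fell in 10 of 15 cases and rose in 3 (median -1.16, camera adjusted p = 0.0151), with TNFRSF1B at -3.54 and TNFRSF11B, osteoprotegerin, at -2.55. Genes with IL symbols, interleukins and their receptors, fell in 21 of 37 cases and rose in 5 (camera adjusted p = 0.0151), with IL6R at -4.88 and IL1R1 at -2.60. SEC genes, many of them of protein translocation and coat assembly, rose in 15 of 25 cases and fell in 2 (camera adjusted p = 0.0118), with SEC61G at 0.88 and SEC23A at 0.68. With total counts as the scale, tried after seeing the data, 9 SEC genes were higher and 7 lower, and their median of 0.27 became -0.01.

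The protocadherin PCDHGA genes had the smallest p of that scan and are not reported as a finding. All 12 had between 203 and 215 CPM in control and between 121 and 129 CPM in TGFβ libraries, and log2 fold changes from -0.75 to -0.73. Between 27.6% and 51.4% of the exonic bases of each overlap those of 1 other gene, so the 12 rows cannot be taken as independent measurements; whether the reads lie on shared exons was not tested. Counts of other overlapping genes are not independent either: ACTA2-AS1 had 168850 counts in TGFβ libraries beside 369960 for ACTA2.

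Other splits of the 6 libraries were counted. Of 10 splits into 3 and 3, 1 gave as many genes as the real 8915, the real one itself, and the highest of the other splits gave 0. Each other split puts control and TGFβ libraries in the same group, so their difference counts as spread and few calls could arise. A share under 0.05 is also out of reach with 10 splits, so the splits decide nothing.

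Proliferation genes were higher with TGFβ. Scaling moves all genes alike, yet the list median lay 0.612 above the median of all tested genes (95% bootstrap interval of the list median 0.36 to 0.75), above all 10000 random lists matched on expression. Random lists and bootstrap treat genes as independent, whereas members of this list had an estimated correlation of 0.264. With an estimated correlation the list did not pass (camera adjusted p = 0.367), a loss that need not come from correlation alone. Gene length and GC content left a median of 0.607 after their trend was subtracted (interval 0.38 to 0.70). Both values argue against these technical causes as the whole of the pattern. Whether more cells were dividing was not tested.

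Interferon response genes were lower with TGFβ. Of 7 abundant immune transcripts 0 reached 1 CPM in the controls, the highest being CD14 at 0.4 ± 0.261 CPM. Some markers on the immune lists were well above that level in the controls and fell with TGFβ, IL7R from 57.9 to 30.1, CD4 from 32.2 to 15.9 and CD68 from 31.3 to 18.2 CPM. Immune cells would bring PTPRC, the leukocyte common antigen, and CD3E or TYROBP with them, and these had 4, 0 and 2 counts over the controls, which argues against immune cells as the source. Whether low-count members carry the fall stays open: the 7 members with at least 10 CPM had a median of -0.973, but its bootstrap interval of -1.20 to -0.10 covers the bound of -0.6 set in advance. The interval was asked for only after that median had been seen. STAT2 and IRF1 fell, with log2 fold changes of -0.97 and -2.22, while ISG15 and DDX58 did not pass the test (0.18 and -0.10).

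Scaling by total counts gave more lower than higher genes. A few abundant genes were a candidate cause, but leaving the 10 most abundant genes out of the totals gave 31.8% higher calls against 50.5% with TMM, more than 10 percentage points away. The offset from TMM was 0.27 with all genes, 0.20 without FN1, 0.15 without the top 10 and 0.05 without the top 500. The 10 genes account for part of the offset and the rest is spread over many genes.

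A fall of NRF2 target genes may go with the fall of antioxidant genes. Of 22 other NRF2 targets 16 fell and 4 rose, the median was -0.793, and none (0) of 10000 random lists matched on expression lay lower. SQSTM1 fell by 0.99 on the log2 scale, while ME1 and UGDH rose by 0.43 and 0.73, so the targets did not move as one. A fall of NF-kB target genes may go with the fall of the cytokine and chemokine list. Of 19 tested targets 14 fell and 2 rose with a median of -0.815, again below all 10000 random lists. TNFAIP2, NFKB1 and PSMB9 fell, with log2 fold changes of -2.06, -0.82 and -3.52, and NFKBIZ rose by 0.78. With an estimated correlation the unadjusted camera p was 0.0238 for NRF2 targets and 0.0112 for NF-kB targets. These are not comparable with the adjusted values given for other lists. The quiescent list had an unadjusted p of 0.0224 there and an adjusted p of 0.367. Both lists were drawn up because related genes had been seen to fall, and neither measures the activity of the factor.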
